A study of Mus musculus with 12 samples.

How the data were processed

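The series holds 12 Affymetrix whole-transcript arrays of the plantaris, a calf muscle made mostly of fast fibres, from male mice aged 12 weeks. The labels place the arrays in 4 groups of 3: wild-type and REDD1 knockout mice, each either sedentary or sampled 1 hour after a single bout of aerobic exercise. Food was withheld from all mice for 3 hours, per the labels. The labels state no pooling and name no litter, batch or hybridisation day. Replicate numbers here follow the order of the samples in the series and pair nothing across groups.

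Per the labels' protocols, biotin-labelled target was made from total RNA with a whole-transcript kit, and Partek is the only software named, without a version. The deposited table gives log2 expression values per transcript cluster, as read from their range of 0.36 to 13.9. The log base, the background correction, the normalisation and the summarisation are not stated by the authors. Array medians lay between 4.52 and 4.60 and upper quartiles between 6.06 and 6.13, so the deposited values had a similar distribution on every array. No value was missing.

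Of the 41345 transcript clusters in the table, 23521 were paired with exactly 1 gene symbol by the platform annotation, 1814 with several and 16010 with none. Of those with 1 symbol, 23328 had a gene identifier found in the mouse reference gene table (assembly GRCm38.p6), and 0 symbols changed on update. For a gene with several clusters, the cluster with the highest mean over the 12 arrays was used, which left 22180 genes. A gene was tested if its value exceeded the median of the whole table, 4.56 on the log2 scale, in at least 3 arrays. This filter kept 13747 genes. Clusters with no gene symbol or several were left out of the comparisons and counted separately. The array's genome build is not named, so the reference table was used only for names and for the order of neighbouring genes.

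Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit, then eBayes with an intensity trend in the prior). A single fit of all 12 arrays had 1 mean per group and 8 residual degrees of freedom, so the groups shared one estimate of the spread. From it, 7 contrasts were drawn: exercise in each genotype, the difference of these exercise effects (knockout minus wild type), knockout against wild type in each condition, and the averages of the exercise and genotype effects. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. All p-values are two-sided unless stated. Values are log2 fold changes with limma's standard error (SE), with 3 arrays per group, or 6 per side for the averages. Where the mean of a compared group lay below the table median, a called gene's difference is given as at least the value with arrays below the median set to it, a rule added after the data were seen.

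Before the data were examined, 28 gene lists were fixed. They covered immediate-early genes, exercise-responsive metabolic genes, glucocorticoid receptor targets, mTORC1 components and regulators, ubiquitin ligase and autophagy genes, heat shock and chaperone genes, the unfolded protein and integrated stress response, hypoxia-inducible genes, cytokine, chemokine and myokine genes, circadian clock genes, neuromuscular junction genes, oxidative phosphorylation subunits, glycolysis and glycogen genes, fast-fibre and slow-fibre contractile genes, myogenic and satellite cell genes, interferon-stimulated genes, p53 target genes and housekeeping controls. Marker lists for other tissue or cells covered extracellular matrix and fibroblasts, tendon, endothelium, smooth muscle and pericytes, macrophages and leukocytes, neutrophils, adipocytes, Schwann cells and nerve, and red blood cells. Ddit4 itself was left out of every list. Lists with at least 5 measured members were tested with camera (preset correlation of 0.01, adjusted over the lists within a contrast). Here and below, measured genes and list members are those that passed the filter. The neutrophil list (4 members measured) and the red blood cell list (2) were not tested. Too dim to be tested were S100a8, S100a9, Retnlg, Ly6g, Mmp8, Camp and Ngp of the neutrophil list and Epb42 of the red blood cell list. So were Il6, Cxcl2, Il1b, Tnf, Cxcl10 and Bdnf of the cytokine list. In other lists, Fgf21, Slc7a11, Gdnf, Pax3, Lep, Nefl, Nefm and Mx1 were too dim. The correlation estimated per list and limma's fry served as alternatives. Each list's level on an array is the mean over its members of the difference from the 12-array mean.

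The rule for named genes was fixed at the same time. It took, per contrast, the 10 largest rises and 10 largest falls among called genes, filled up to 20 by the smallest unadjusted p where fewer passed, together with Ddit4 and up to 4 members per list. Predicted or unnamed gene models were counted and not named. The 40 measured genes nearest Ddit4, 20 on each side, were tested as a group, because a knockout made in cells of another strain can carry that strain's DNA beside the target.

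The analysis was tested on simulated data with the real genes' means and spreads, with 200 of 13747 genes changed in the wild type alone. For exercise in wild type, 38.0% of genes changed by 0.5 on the log2 scale were recovered, 89.5% of those changed by 1 and 99.1% of those changed by 2, and 6.18% of calls were false. For the difference of exercise effects, recovery was 9.63%, 69.3% and 96.3% at the same sizes, with 5.16% of calls false. The average over genotypes takes up only part of a change made in the wild type alone. For it, recovery was 8.22%, 72.1% and 96.3% at these wild-type sizes, with 4.01% of calls false. Changes shared by both genotypes were not simulated, so these shares do not give the recovery of such changes. Recovery also depends on how many genes change, because the Benjamini-Hochberg cutoff loosens as more genes differ. With fewer than 200 changed genes it would be lower. The shares therefore do not show that differences of these sizes would have been called in the real data. A list of 20 genes shifted by 0.3 passed camera at an unadjusted p under 0.05 in 50 of 50 runs, and an unshifted list in 2 of 50. The simulated genes varied independently of each other. These rates therefore do not hold for lists whose members vary together, for which the preset correlation can give too small a p.

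Alternatives fixed before the data were examined were no filter, a stricter filter (7166 genes), all transcript clusters tested one by one, quantile normalisation, median centring, no trend in the prior, array weights, fits of only the groups compared, analysis of variance without moderation, other thresholds, 10 instead of 20 neighbours on each side of Ddit4, and each of the 12 arrays left out in turn. A pair of alternatives was added after the data were seen. In the first, both arrays that stood apart in list levels were left out. In the second, the difference of exercise effects was tested only over genes called for the averaged exercise effect.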

Results

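Gene expression was measured on 12 arrays of plantaris muscle, 3 from each of 4 groups: wild-type sedentary, wild-type exercised, REDD1 knockout sedentary and REDD1 knockout exercised. REDD1, the product of the gene Ddit4, is a stress-induced inhibitor of mTORC1, the kinase complex that drives protein synthesis. Exercised mice were sampled 1 hour after a single bout of aerobic exercise. Pearson's r between arrays across transcript clusters ranged from 0.967 to 0.985, with a mean of 0.978 within groups and 0.977 between them. The number of arrays limits the precision. Some arrays stood apart from the others of their group in the level of fixed gene lists. In knockout sedentary replicate 3, the extracellular matrix and fibroblast markers lay 0.96 above the 12-array mean on the log2 scale, against 0.17 and -0.15 in the other knockout sedentary arrays. In wild-type exercised replicate 1, the immediate-early genes lay 0.78 above the mean, against 0.09 and 0.24 in the other wild-type exercised arrays. The Schwann cell and nerve markers were highest on these arrays, at 0.67 and 0.78, and were also high on knockout exercised replicate 2, at 0.52.

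Ddit4 was lower in the knockout arrays than in the wild-type arrays of the same condition, without overlap in either condition. Its log2 levels were 6.13, 5.83 and 6.02 in wild-type sedentary, 9.05, 8.40 and 8.62 in wild-type exercised, 5.32, 5.44 and 5.08 in knockout sedentary and 6.46, 5.72 and 6.77 in knockout exercised arrays. Groups of 3 against 3 fail to overlap by chance in 10% of cases. Averaged over conditions, Ddit4 was 2.91-fold lower in the knockout (log2 fold change -1.54, SE 0.16, adjusted p = 0.000137). The part of the gene that was deleted and the place of the array's probes are not given, so the remaining signal cannot be assigned to an intact or a shortened transcript.

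**Figure D1:**
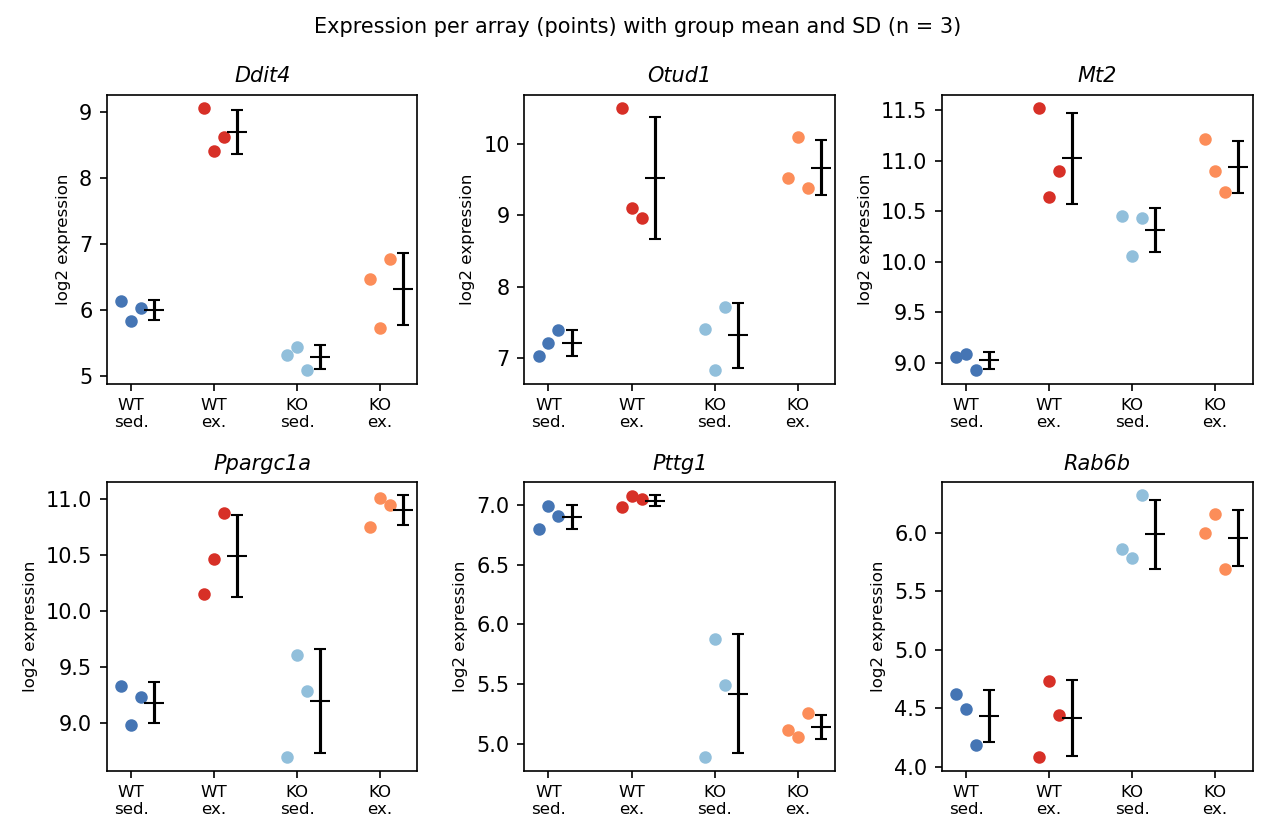
Log2 expression of 6 genes on each of the 12 arrays (points), with the mean and SD of each group (n = 3, bars). Ddit4 rose from a mean of 5.99 to 8.69 with exercise in wild type and stood at 5.28 and 6.32 in sedentary and exercised knockout, while Pttg1 and Rab6b differed by genotype in both conditions.

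The first comparison asked how plantaris responds to exercise when REDD1 is present. The immediate-early, exercise-responsive metabolic, glucocorticoid and heat shock lists rose in wild-type muscle 1 hour after exercise, with their tests given in the account of the lists. Ddit4 itself rose most, 6.49-fold (log2 fold change 2.70, SE 0.22, adjusted p = 4.73e-05, n = 3 per group). It was followed by the deubiquitinase gene Otud1 (2.32, SE 0.33), the contraction-induced nuclear receptors Nr4a3 (2.11, SE 0.40) and Nr4a2 (2.07, SE 0.40), and the metal-binding metallothionein Mt2 (2.00, SE 0.18). The falls included the apelin receptor gene Aplnr at -1.05 (SE 0.18), the arterial ligand gene Efnb2 at -0.79 (SE 0.14) and the VEGF receptor gene Kdr at -0.76 (SE 0.12). Kdr was the 1 of 12 endothelial markers called; that list did not pass in wild type (median -0.11, 5 of 12 positive, camera adjusted p = 0.0799). The largest fall was that of Rassf9, at -1.20 (SE 0.14, adjusted p = 0.000621). In all, limma called 78 genes, 65 higher and 13 lower after exercise, 34 of them by at least 2-fold. All 20 named genes that passed had groups without overlap. Such genes were chosen on adjusted p and fold change in the same arrays. Their lack of overlap, here and in the later comparisons, is therefore no separate support.

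Among the fixed lists, 23 of 28 measured immediate-early genes had positive values and the list's median was 0.74 (camera adjusted p = 1.77e-24). Of them 9 rose, and 17 when adjusted over the list alone, among them Fosl2 (1.36), Csrnp1 (1.37) and Klf4 (1.12). The exercise-responsive metabolic genes had a median of 0.20, with 4 of 19 rising (8 adjusted over the list alone): the kinase gene Sik1 (1.72), Slc25a25, a mitochondrial ATP-magnesium carrier (1.92), Irs2, an insulin receptor substrate (1.41), and Ppargc1a, the coactivator of mitochondrial biogenesis (1.31). The glucocorticoid receptor targets had a median of 0.67, with 7 of 22 rising (15 adjusted over the list alone), led by Mt2, Mt1 (1.62), the clock gene Per1 (1.34) and the transcription factor gene Cebpd (1.34). The heat shock and chaperone genes were all positive, 16 of 16, with a median of 0.16; 0 were called by limma over all genes and 4 adjusted over the list alone. These 4 lists also passed with an estimated correlation (adjusted p = 0.0193, 0.0193, 0.0193 and 0.0391). A further 4 passed with the preset correlation only, and not by fry. The median of the unfolded protein and integrated stress response was 0.10 (adjusted p = 0.257 with an estimated correlation), and that of the macrophage and leukocyte markers 0.06 (adjusted p = 0.557 with an estimated correlation). The adipocyte markers had a median of 0.29 (adjusted p = 0.284 with an estimated correlation), and the Schwann cell and nerve markers 0.42 (adjusted p = 0.557 with an estimated correlation). The last of these was 0.14 and no longer passed without wild-type exercised replicate 1, the array with high levels of these markers and of the immediate-early genes. Of the 20 named genes, 12 passed with any 1 of the 12 arrays left out; the others were Aplnr, Efnb2, Hoxa2, Nr4a2, Nr4a3, Tnk2, Zfp157 and Zfp608. Of the 8 lists, 5 did so, the macrophage, Schwann cell and unfolded protein lists being the exceptions. The count for exercise in wild type was 46 without wild-type sedentary replicate 1, 46 without wild-type exercised replicate 3, and 12 by analysis of variance without moderation.

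The same comparison in knockout muscle asked what the response looks like without REDD1. Otud1 rose 5.12-fold (log2 fold change 2.36, SE 0.33, adjusted p = 0.00348, n = 3 per group) and Nr4a3 4.59-fold (2.20, SE 0.40). Ppargc1a rose by 1.70 (SE 0.20), Irs2 by 1.58 (SE 0.14), the vitamin B6 kinase gene Pdxk by 1.43 (SE 0.17) and the phosphate transporter gene Slc20a1 by 1.47 (SE 0.14). Impact, an inhibitor of the amino acid sensor GCN2, rose by 1.57 (SE 0.13, adjusted p = 7.19e-05). Kdr fell by 0.84 (SE 0.12), Sema6a by 0.98 (SE 0.16) and the lysophosphatidic acid receptor gene Lpar4 by 0.83 (SE 0.14). Ddit4 was 2.05-fold higher after exercise but did not pass (1.04, SE 0.22, adjusted p = 0.0679). In all, 38 genes were called, 33 higher and 5 lower, 16 of them by at least 2-fold, and all 14 named genes that passed had groups without overlap.

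In the knockout, 13 of 28 immediate-early genes rose when adjusted over the list alone and 1, Nr4a3, over all genes (list median 0.49). The metabolic genes had a median of 0.24, with 4 of 19 called and 7 adjusted over the list alone, including Hk2, the hexokinase of muscle (0.86). The glucocorticoid receptor targets had a median of 0.52, with 2 of 22 called, Cebpd (1.11) and Cebpb (0.72), and 12 adjusted over the list alone. Heat shock and chaperone genes were again all positive, with a median of 0.28, 1 of 16 called (Hsp90aa1, 0.56) and 6 adjusted over the list alone. The unfolded protein and integrated stress response had a median of 0.14, with 0 of 18 called by limma and 6 adjusted over the list alone. Vascular markers were lower after exercise. The endothelial median was -0.25, with 1 of 12 called (Kdr) and 4 lower when adjusted over the list alone, and the smooth muscle and pericyte median was -0.24, with 0 of 10 called by limma and 2 adjusted over the list alone. These 7 lists also passed with an estimated correlation (adjusted p between 0.0282 and 0.0379).

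A further 8 lists passed camera in the knockout with the preset correlation and not with an estimated one; of these, the ubiquitin ligase (adjusted p = 0.0387), hypoxia-inducible (adjusted p = 0.0401) and tendon lists (adjusted p = 0.0466) passed by fry. The extracellular matrix and fibroblast median was -0.47 (adjusted p = 0.135 with an estimated correlation), with 0 of 15 members called by limma and 11 lower when adjusted over the list alone. It was -0.26 without knockout sedentary replicate 3, the array with the highest level of these markers. The tendon median was -0.24 (adjusted p = 0.0793 with an estimated correlation), the macrophage and leukocyte median -0.17 (adjusted p = 0.364 with an estimated correlation) and the interferon-stimulated median -0.17 (adjusted p = 0.135 with an estimated correlation). Positive medians were 0.10 for the ubiquitin ligase and autophagy genes (adjusted p = 0.0668 with an estimated correlation) and 0.09 for the hypoxia-inducible genes (adjusted p = 0.0953 with an estimated correlation). They were 0.12 for the oxidative phosphorylation subunits (adjusted p = 0.285 with an estimated correlation) and 0.28 for the slow-fibre contractile genes (adjusted p = 0.442 with an estimated correlation). Slow-fibre levels varied among knockout sedentary arrays from -0.47 to 0.44, the latter in replicate 3. Of the 14 named genes that passed, 8 did so with any 1 of the 12 arrays left out; the others were Adamts9, Ciart, Lpar4, Nr4a3, Sema6a and Sp100. Of the 15 lists, 11 did so, the hypoxia, interferon, macrophage and slow-fibre lists being the exceptions. The count for exercise in knockout was 16, 19 and 20 without knockout exercised replicate 1, knockout exercised replicate 3 and knockout sedentary replicate 1, 71 without wild-type exercised replicate 1, and 0 by analysis of variance without moderation (limma's unadjusted p was under 0.05 for 1227 genes).

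The central question of the design, whether the response depends on REDD1, is tested by the difference of exercise effects. No single gene passed over all genes. Limma called 0 of 13747 (smallest adjusted p = 0.633), with an unadjusted p under 0.05 for 620 genes where 687.4 are expected by chance, and analysis of variance without moderation also called 0. The genes with the smallest unadjusted p were Ddit4 (knockout minus wild type, -1.66, SE 0.31) and Mt2 (-1.38, SE 0.26). Mt2 rose by 2.00 in wild type and stood 0.62 higher in the knockout, where it did not pass (adjusted p = 0.245). Its sedentary levels were 9.06, 9.09 and 8.93 in wild type and 10.45, 10.06 and 10.43 in the knockout. Its exercised levels overlapped, at 11.52, 10.64 and 10.90 in wild type and 11.21, 10.90 and 10.69 in the knockout. The smaller rise of Mt2 thus went with a higher resting level in the knockout. The effects in the genotypes correlated across all genes with Pearson's r = 0.381 (jackknife SE over arrays 0.083) and Spearman's rho = 0.233. Over the 96 genes called in either genotype, r was 0.791 and rho 0.663. Genes are not independent replicates, so no p is given. Between the genotypes, 20 called genes were shared, all in the same direction, where independent lists of these sizes would share 0.22. The lists are not independent, since both contrasts use the same estimate of each gene's spread, which can raise the overlap. All 78 genes called in wild type had the same sign in the knockout. Of the 58 called in wild type alone, 45 had an unadjusted p under 0.05 with the same sign there. Over all 13747 genes, 1227 had an unadjusted p under 0.05 in the knockout. The shared spread can raise the count of 45 as well. The difference of exercise effects had an unadjusted p under 0.05 for 26 of these 58, a count raised by choosing genes on the wild-type call. It did so for 32 of the 220 genes called for exercise averaged over genotypes. There, 11 would be expected if choosing genes on the averaged call had no influence. Both contrasts use the same estimate of each gene's spread, so this choice can raise the count of 32 too. In the other direction, 37 of the 38 genes called in the knockout had the same sign in wild type. Of the 18 called in the knockout alone, 11 had an unadjusted p under 0.05 with the same sign there. Over all 13747 genes, 1128 had an unadjusted p under 0.05 in wild type, and the same limit holds. Over the genes called in wild type, the median ratio of the knockout's to the wild type's log2 fold change was 0.647, and over the genes called in the knockout, the median ratio of the wild type's to the knockout's was 0.792. Each ratio is lowered by choosing genes on its denominator.

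**Figure D2:**
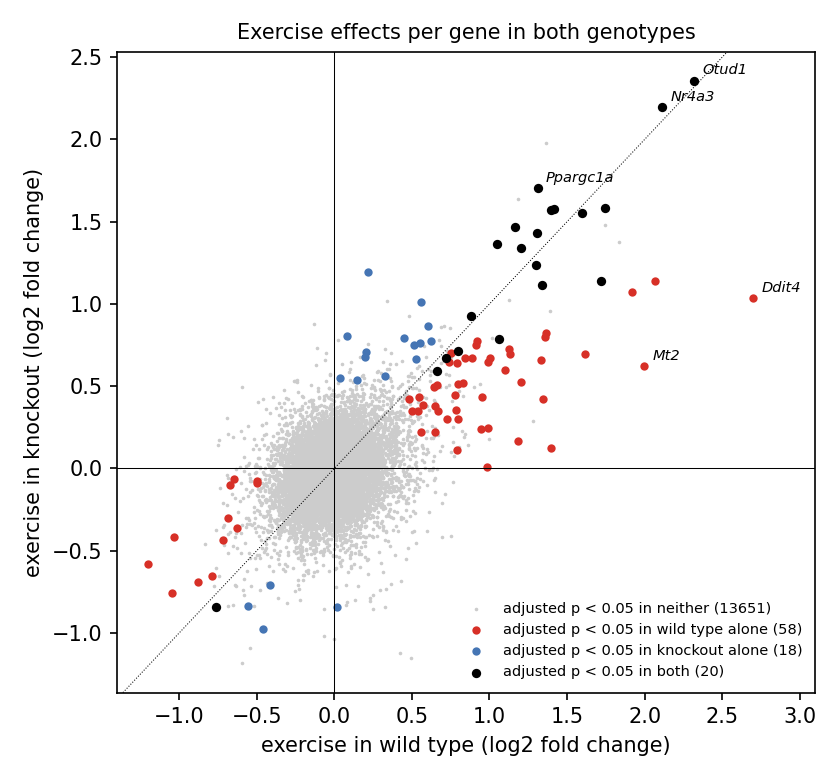
Log2 fold change with exercise in wild type (horizontal axis) and in knockout (vertical axis) for the 13747 genes tested, coloured by where limma's adjusted p was under 0.05: 58 genes in wild type alone, 18 in knockout alone and 20 in both. The dotted line marks equal effects; Ddit4 lies below it at 2.70 and 1.04.

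At the level of lists, 11 of 26 passed camera for the difference, 2 with a more positive and 9 with a more negative effect in the knockout, and 0 passed with an estimated correlation or by fry. With any 1 of the 12 arrays left out, 5 of the 11 passed each time: the matrix, macrophage, smooth muscle, tendon and ubiquitin ligase lists. The extracellular matrix and fibroblast markers had the largest difference, a median of -0.55 with 15 of 15 members negative (adjusted p = 0.231 with an estimated correlation). No member was called by limma over all genes and 7 were lower when adjusted over the list alone. The median was -0.36 without knockout sedentary replicate 3, the array with high matrix markers. The immediate-early genes had a median of -0.22 (adjusted p = 0.41 with an estimated correlation), which turned to 0.03 without wild-type exercised replicate 1. The glucocorticoid receptor targets had a median of -0.19 (adjusted p = 0.315 with an estimated correlation), which no longer passed without wild-type sedentary replicate 2 (-0.12) or wild-type exercised replicate 1 (-0.18).

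Averaging the effect of exercise over genotypes, with 6 arrays on each side, asked how exercise acts across both genotypes and gave the most calls of the 7 comparisons. The immediate-early, metabolic, glucocorticoid and heat shock lists rose and the endothelial markers fell, as the list tests show. Otud1 rose 5.06-fold (log2 fold change 2.34, SE 0.23, adjusted p = 4.64e-05) and Nr4a3 4.45-fold (2.15, SE 0.28). The inducible chaperone gene Hspa1b rose by 1.67 (SE 0.30), the clock repressor gene Ciart by 1.66 (SE 0.17), the stress transcription factor gene Atf3 by 1.61 (SE 0.32), the growth inhibitor gene Btg2 by 1.61 (SE 0.29) and Ppargc1a by 1.51 (SE 0.14). In wild type, much of the rise of Hspa1b, Atf3 and Btg2 lay on exercised replicate 1, which stood apart. Wild-type exercised levels in replicates 1, 2 and 3 were 9.070, 6.808 and 6.735 for Hspa1b and 10.059, 7.585 and 7.966 for Atf3. They were 9.661, 7.285 and 8.01 for Btg2. Knockout exercised levels were closer together, as for Hspa1b at 7.999, 8.213 and 7.892. Aplnr fell by 0.90 (SE 0.13), Kdr by 0.80 (SE 0.09), Efnb2 by 0.72 (SE 0.10) and the glycerol channel gene Aqp7 by 0.68 (SE 0.14). Of 220 called genes, 150 were higher and 70 lower; with median centring, 149 were higher and 41 lower. All 20 named genes had groups without overlap in both genotypes.

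Over the averaged effect, 12 of 28 immediate-early genes rose (19 adjusted over the list alone; median 0.58), 7 of 19 metabolic genes (8; 0.19) and 13 of 22 glucocorticoid receptor targets (19; 0.65). Of 16 heat shock and chaperone genes 5 rose (9 adjusted over the list alone; median 0.23), including Hspa1a (1.41), Hsp90aa1 (0.44) and Dnajb1 (0.53). In the unfolded protein and integrated stress response, 1 of 18 rose, Dnajb9 (0.37), and 8 adjusted over the list alone. Among endothelial markers 2 of 12 fell, Kdr and Cdh5 (-0.28), and 5 adjusted over the list alone (median -0.24). These 6 lists also passed with an estimated correlation (adjusted p between 0.00997 and 0.0459). The ubiquitin ligase and autophagy genes had 2 of 20 called, Trim63, a muscle ubiquitin ligase that is also on the glucocorticoid list (0.79), and Gabarapl1 (0.41), with a median of 0.07 (adjusted p = 0.218 with an estimated correlation). The p53 targets had 2 of 12 called, Btg2 and Trp53inp1 (0.70), with a median of 0.09 (adjusted p = 0.127 with an estimated correlation). The interferon-stimulated median was -0.20 (adjusted p = 0.156 with an estimated correlation, adjusted p = 0.0494 by fry) and that of the smooth muscle and pericyte markers -0.11 (adjusted p = 0.162 with an estimated correlation). The extracellular matrix and fibroblast median was -0.26 (adjusted p = 0.468 with an estimated correlation) and was -0.06 without knockout sedentary replicate 3, where the list no longer passed. The other 4 lists called with the preset correlation were tendon (median -0.11, adjusted p = 0.41 with an estimated correlation), oxidative phosphorylation (0.05, adjusted p = 0.468 with an estimated correlation), slow-fibre (0.16, adjusted p = 0.468 with an estimated correlation) and Schwann cell markers (0.30, adjusted p = 0.518 with an estimated correlation). Schwann cell levels in the wild-type exercised arrays were 0.78 in replicate 1 and -0.412 and -0.045 in the others. In knockout exercised replicates 1, 2 and 3 they were -0.355, 0.52 and 0.282. The count for exercise averaged over genotypes was 144 without wild-type sedentary replicate 1 or wild-type exercised replicate 3, and 67 by analysis of variance without moderation. Of the 20 named genes, 18 passed with any 1 of the 12 arrays left out, Aqp7 and Atf3 being the exceptions. Of the 15 lists, 8 did so; the others were the matrix, oxidative phosphorylation, p53, Schwann cell, slow-fibre, smooth muscle and tendon lists.

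**Figure D3:**
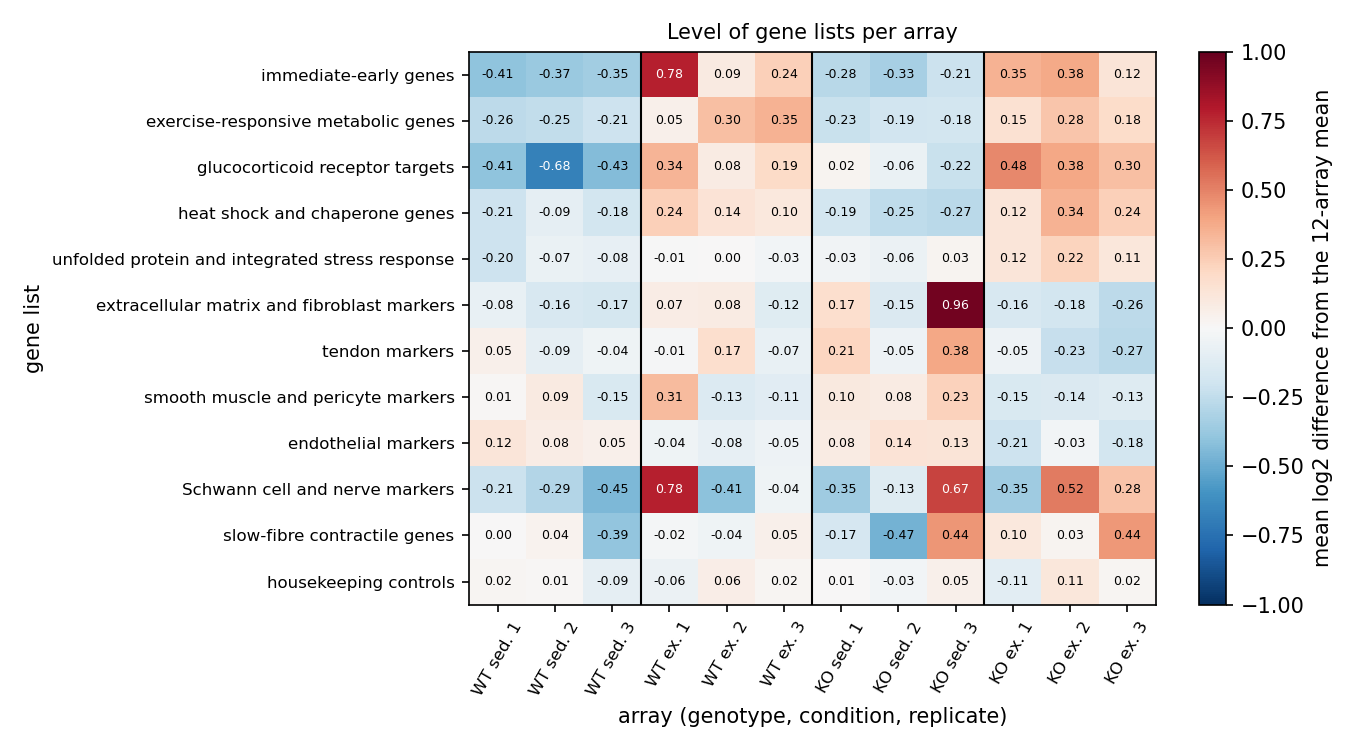
Mean level of 12 fixed gene lists on each of the 12 arrays, as the log2 difference from the mean of all arrays (colour and printed value). The immediate-early and glucocorticoid lists lay below the mean on every wild-type sedentary array and above it on every exercised array, and the extracellular matrix list reached 0.96 on knockout sedentary replicate 3.

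Knockout against wild type in sedentary mice asked how the genotypes differ at rest. The labels name no litter or batch, and the genes called for the averaged genotype effect were grouped along the genome, as weighed below. Aldh4a1 and Iigp1 lie in such runs of neighbours. Differences in this and the later genotype comparisons therefore cannot be assigned to loss of REDD1 alone. Few genes differed. Pttg1, the gene of securin, an inhibitor of the separation of sister chromatids, was 2.79-fold lower in the knockout (log2 fold change -1.48, SE 0.18, adjusted p = 0.00257, n = 3 per group). Rab6b, a Golgi transport GTPase gene, was at least 2.65-fold higher (adjusted p = 0.00257), a bound because its wild-type level of 4.43 lies below the median of the table. Mt2 was higher by 1.29 (SE 0.18), Ddost, a subunit of the N-glycosylation enzyme, by 0.998 (SE 0.11), and Hsd17b7, an enzyme of cholesterol synthesis, by 0.98 (SE 0.14). Aldh4a1, a mitochondrial enzyme of proline breakdown, was lower (-0.91, SE 0.12). The ribonuclease gene Rnase2a was also called as higher (adjusted p = 0.0405), but its wild-type level of 3.09 lay below the table median too, so that the difference is at least 1.59-fold, and the call was lost under 14 of 23 alternatives. Limma called 19 genes, 6 higher and 13 lower, and Ddit4 was not among them (-0.71, SE 0.22, adjusted p = 0.411). All 17 named genes that passed had groups without overlap.

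All 22 glucocorticoid receptor targets had positive values in the sedentary knockout, with a median of 0.28 (camera adjusted p = 6.16e-14; adjusted p = 0.148 with an estimated correlation). Mt2 was the 1 member called, and 8 were higher when adjusted over the list alone. The extracellular matrix and fibroblast markers had a median of 0.39 (adjusted p = 0.396 with an estimated correlation), with 0 of 15 called by limma and 4 adjusted over the list alone, and the median was 0.15 without knockout sedentary replicate 3. The oxidative phosphorylation subunits had a median of -0.12 with 3 of 23 positive (adjusted p = 0.428 with an estimated correlation) and the glycolysis and glycogen genes -0.06 (adjusted p = 0.469 with an estimated correlation). Other lists called with the preset correlation had medians of 0.23 for p53 targets (adjusted p = 0.18 with an estimated correlation) and 0.25 for adipocyte markers (adjusted p = 0.405 with an estimated correlation). The medians were 0.15 for macrophage and leukocyte markers, 0.36 for Schwann cell and nerve markers and 0.12 for immediate-early genes (each with adjusted p = 0.469 with an estimated correlation). They were 0.13 for tendon markers (adjusted p = 0.447 with an estimated correlation) and 0.07 for cytokine, chemokine and myokine genes (adjusted p = 0.314 with an estimated correlation). Schwann cell and nerve levels were -0.355, -0.128 and 0.673 in the knockout sedentary arrays, the last in replicate 3. In the wild-type sedentary arrays they were -0.215, -0.291 and -0.453. In all 11 lists passed with the preset correlation and 0 with an estimated correlation or by fry. For knockout against wild type, sedentary, the count was 6 without knockout sedentary replicate 1, 12 without wild-type sedentary replicate 1, and 1 by analysis of variance without moderation. With any 1 of the 12 arrays left out, 4 of the 17 named genes passed each time, Aldh4a1, Ddost, Pttg1 and Rab6b, and 2 of the 11 lists, the matrix and glucocorticoid lists.

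Knockout against wild type after exercise asked how the exercised muscles differ by genotype. Ddit4 was 5.18-fold lower in the knockout (log2 fold change -2.37, SE 0.22, adjusted p = 0.00011, n = 3 per group) and Pttg1 3.71-fold lower (-1.89, SE 0.18). The interferon-induced GTPase gene Iigp1 was 5.28-fold lower (-2.40, SE 0.35) and the acute-phase protein gene Orm1 2.11-fold lower (-1.08, SE 0.16). Rab6b (at least 2.52-fold, from a wild-type level of 4.42 below the table median) and Ddost (0.91, SE 0.11) were higher, as in sedentary mice, together with Sesn1, an inhibitor of mTORC1 and a member of the mTORC1, p53 and glucocorticoid lists (0.84, SE 0.16, adjusted p = 0.0495), and the arrestin-domain gene Arrdc3 (0.81, SE 0.13). Limma called 24 genes, 13 higher and 11 lower; with quantile normalisation, 11 were higher and 15 lower. All 20 named genes had groups without overlap.

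After exercise, 17 of 18 genes of the unfolded protein and integrated stress response had positive values in the knockout relative to wild type, with a median of 0.18 (adjusted p = 0.169 with an estimated correlation). The ubiquitin ligase and autophagy genes had a median of 0.13 (adjusted p = 0.169 with an estimated correlation), with 0 of 20 called by limma and, adjusted over the list alone, 4 higher and 1 lower. The p53 targets had a median of 0.16 (adjusted p = 0.169 with an estimated correlation) and the glucocorticoid receptor targets 0.13 (adjusted p = 0.453 with an estimated correlation). The extracellular matrix and fibroblast median was -0.18 (adjusted p = 0.791 with an estimated correlation) and the tendon median -0.16 (adjusted p = 0.453 with an estimated correlation). For knockout against wild type, exercised, the count was 5, 12, 7 and 13 without wild-type exercised replicate 3, wild-type exercised replicate 2, knockout exercised replicate 1 and knockout exercised replicate 2, 40 without wild-type exercised replicate 1, and 1 by analysis of variance without moderation. With any 1 of the 12 arrays left out, 4 of the 20 named genes passed each time, Ddit4, Ddost, Pttg1 and Rab6b, and 2 of the 6 lists, the ubiquitin ligase and unfolded protein lists.

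The genotype effect averaged over exercise, with 6 arrays per side, asked what separates the genotypes in both conditions. Pttg1 (log2 fold change -1.69, SE 0.13, adjusted p = 7.18e-06), Rab6b (at least 2.59-fold higher, from wild-type levels below the table median) and Ddost (0.96, SE 0.08) again differed. They were joined by Iigp1 (-1.96, SE 0.24), Tirap, an adaptor of Toll-like receptors (-0.89, SE 0.12), and Aqp4, the water channel of fast fibres (-0.70, SE 0.10). The cell cycle inhibitor gene Cdkn1a was higher by 0.67 (SE 0.14, adjusted p = 0.0491) and cardiac actin Actc1 was lower (-1.34, SE 0.24), but their groups overlapped in at least 1 condition, as did those of Rps13 and Fam107a. The call of Cdkn1a was lost under 14 of 23 alternatives, quantile normalisation and median centring among them, and that of Actc1 under 5 of 23. Limma called 75 genes, 29 higher and 46 lower. The predicted gene 2610507I01Rik, named here after its values were seen, was lower by at least 3.24-fold (adjusted p = 2.52e-08), with knockout levels below the table median.

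Over the averaged genotype effect, the glucocorticoid receptor targets had a median of 0.31 with 21 of 22 positive (adjusted p = 0.0902 with an estimated correlation). Of these, 2 were called, Sesn1 (0.54) and Cdkn1a (0.67), and 12 were higher when adjusted over the list alone. Both are also p53 targets, a list with a median of 0.20 (adjusted p = 0.0902 with an estimated correlation). The unfolded protein and integrated stress response had a median of 0.12 (adjusted p = 0.0956 with an estimated correlation). These 3 lists passed by fry (each adjusted p = 0.0375). The ubiquitin ligase and autophagy median was 0.06 (adjusted p = 0.499 with an estimated correlation) and the oxidative phosphorylation median -0.09 (adjusted p = 0.976 with an estimated correlation). The count for genotype averaged over exercise was 38 without wild-type sedentary replicate 2, 40 and 43 without wild-type exercised replicates 3 and 2, 42 without knockout sedentary replicate 2, and 45 without wild-type sedentary replicate 3, knockout exercised replicate 1 or knockout exercised replicate 2. It was 149 without wild-type exercised replicate 1 and 23 by analysis of variance without moderation. Of the 20 named genes, 16 passed with any 1 of the 12 arrays left out; the others were Actc1, Cdkn1a, Fam107a and Rps13. Of the 5 lists, 3 did so, the oxidative phosphorylation and ubiquitin ligase lists being the exceptions.

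The mTORC1 components and regulators, the pathway on which REDD1 acts, passed as a list in none of the 7 comparisons. Their median in knockout against wild type was -0.003 in sedentary mice (camera adjusted p = 0.816) and 0.04 in exercised mice (camera adjusted p = 0.168). With exercise, averaged over genotypes, the medians were -0.01 for mTORC1 genes, -0.006 for fast-fibre contractile genes, -0.045 for myogenic and satellite cell genes, 0.015 for circadian clock genes and 0.002 for housekeeping controls, and none of these 5 lists passed camera in any comparison. Single members passed there: Myod1, the myogenic master regulator, fell by 0.63, and the clock genes Ciart, Per1 (0.88), Nfil3 (0.72) and Cry2 (0.34) rose. For the clock list in wild type, the median (-0.05) and the mean (0.10) differed in sign and camera's direction was up (adjusted p = 0.367). Among lists that passed camera, the median, the mean and the test had the same sign in every comparison. Of the 40 measured genes nearest Ddit4, limma called 0 for genotype averaged over exercise, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.053, and analysis of variance without moderation also called 0. Their median was -0.02 (camera p = 0.582; p = 0.681 with an estimated correlation).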

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

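The tests on the matrix markers and on the glucocorticoid receptor targets, and the test of the difference of exercise effects over a smaller set of genes, were chosen after those results were seen; the tests of position in the genome were set before.

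When the difference of exercise effects was adjusted only over the 220 genes called for exercise averaged over genotypes, 7 genes passed. Among them is Ddit4, the knocked-out gene itself. The 220 genes were chosen with the same estimates of spread that enter the test, so these adjusted p-values may be too small. Smaller rises or larger falls in the knockout were found for Ddit4 (difference -1.66, adjusted p = 0.0101), Mt2 (-1.38, adjusted p = 0.0101), the acute-phase gene Orm1 (-1.02, adjusted p = 0.0275) and the olfactory receptor gene Olfr1219, named after its values were seen (-0.86, adjusted p = 0.0275). Apbb3 (-0.68, adjusted p = 0.031) and A4galt (-0.68, adjusted p = 0.0359) went the same way. For Mt2, the sedentary level was higher in the knockout and the exercised levels of the genotypes overlapped. Atrnl1, which fell in wild type by 0.65 and stood at -0.06 in the knockout, had a positive difference (0.59, adjusted p = 0.031). Each of these differences had an adjusted p of 0.633 or more over all 13747 genes.

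Camera gave a difference between the genotypes' exercise responses for 11 lists, and 0 of them passed with an estimated correlation. Negative medians were found for extracellular matrix and fibroblast markers (-0.55, weighed below), smooth muscle and pericyte markers (-0.36), adipocyte markers (-0.35), tendon markers (-0.30), macrophage and leukocyte markers (-0.28), immediate-early genes (-0.22), neuromuscular junction genes (-0.20), glucocorticoid receptor targets (-0.19) and cytokine, chemokine and myokine genes (-0.16). Smooth muscle and pericyte levels in the wild-type exercised arrays were 0.313 in replicate 1 and -0.133 and -0.114 in the others. Positive medians were found for ubiquitin ligase and autophagy genes (0.16) and oxidative phosphorylation subunits (0.10). Of these 11 lists, 5 passed with any 1 of the 12 arrays left out; the adipocyte, cytokine, glucocorticoid, immediate-early, neuromuscular junction and oxidative phosphorylation lists did not, and the immediate-early median turned to 0.028 without wild-type exercised replicate 1. For the lists not given elsewhere with it, the adjusted p with an estimated correlation was 0.231 for tendon, smooth muscle, cytokine and ubiquitin ligase genes, 0.251 for macrophage and adipocyte markers, 0.311 for neuromuscular junction genes and 0.596 for oxidative phosphorylation subunits.

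Among transcript clusters outside the comparisons, 7072 without a gene symbol and 1048 with several were bright enough to be tested. With each kind of cluster adjusted together with all others, exercise averaged over genotypes called 30 without a symbol and 5 with several, of 157 in all. Genotype averaged over exercise called 34 without a symbol and 4 with several, of 82 in all.

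The genes called for genotype averaged over exercise were grouped along the genome: 18 of 74 had another called gene among the 10 measured genes on either side, against a median of 8 and a 95th percentile of 14 in 10000 random draws (permutation p = 0.004). Another strain's DNA beside Ddit4, left from the making of the knockout, stays open: 0 of its 40 nearest measured genes were called, but only 0.218 would be expected at the share of all tested genes, and the share of 10% set beforehand as the bound was assumed, not measured. Blocks of another strain's DNA elsewhere in the genome are consistent with the 18 neighbours, which form 8 runs such as Otud3, Capzb and Aldh4a1, or Gramd3, Ctxn3 and Iigp1. For comparison, 70 of 218 genes called for exercise averaged over genotypes had such a neighbour, below the 95th percentile of 73 in random draws. Such blocks could act through real expression differences or through probes that bind one strain's sequence better; which of these holds, and whether some of the runs follow from loss of REDD1, was not tested.

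The extracellular matrix and fibroblast markers fell with exercise in the knockout relative to wild type by camera with the preset correlation (median -0.55), but not with an estimated correlation (adjusted p = 0.231), and knockout sedentary replicate 3 held the highest level of them. A lower share of muscle fibre RNA on that array would raise the markers of other cell types alike. The endothelial markers argue against it: they stood 0.027 above the other 5 sedentary arrays (quartiles -0.08 and 0.13), against 0.73 for the matrix markers (quartiles 0.546 and 1.495). The endothelial and macrophage lists pooled had a median of 0.038 over 26 members, which by the rule set for this test counts against it. The Schwann cell and nerve markers go with a lower fibre share, at 0.905 (quartiles 0.723 and 1.301), and the macrophage markers partly so, at 0.28. Tendon (0.113), smooth muscle and pericyte (0.17) and adipocyte markers (0.134) were positive but lower. Fast-fibre genes stood at -0.083 (quartiles -0.129 and -0.005) and slow-fibre genes at 0.343. As the lists differ, a lower fibre share stays open. More connective tissue in that sample stays open, since the median was -0.36 without that array (adjusted p = 6.39e-09), between the bounds set for and against it. A genotype-dependent effect of exercise on matrix genes also stays open, as the design allows it.

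All 22 glucocorticoid receptor targets had positive values in sedentary knockout against sedentary wild type, with a median of 0.28, and the list passed camera with the preset correlation only (adjusted p = 0.148 with an estimated correlation, adjusted p = 0.119 by fry). A single array as the source is argued against: with each of the 6 sedentary arrays left out in turn, the median stayed between 0.19 and 0.40, and camera's adjusted p with the preset correlation reached 1.46e-07 at most. Another hour of sampling stays open, because the median size of change of 16 clock genes outside the list (0.12) lay at percentile 81 of 10000 matched random lists, between the bounds set for and against it. Handling shortly before the tissue was taken also stays open, with the immediate-early genes at a median of 0.12 (adjusted p = 0.469 with an estimated correlation). A higher glucocorticoid tone or response in the absence of REDD1 may be a biological explanation, which these data leave untested.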

How the results depend on the processing

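Results for both arrays that stood apart left out, and for the difference tested over 220 genes, come from alternatives chosen after the data were seen; all others were planned. Across all alternatives, 153 values of the comparisons stayed within 1.5 times or their jackknife error and 60 moved. A count of 0 that stayed at 0 was scored as unmoved, as for the difference of exercise effects with any array left out. The jackknife error of the agreement came from the same leave-one-out fits that were judged by it. The tally therefore overstates stability. Named genes kept their side of the threshold in 2695 cases, lost it in 436, gained it in 41 and reversed in 0; called lists kept it in 1041, lost it in 235 and reversed in 2. Quantile normalisation and median centring moved none of the 7 total counts of called genes by over 1.5 times, and shifted the median gene by at most 0.015. Within exercise averaged over genotypes, the genes called lower went from 70 to 41 with median centring. Causes not named here were not tested.

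The agreement of the exercise effects (r = 0.381) was 0.249 with no filter on dim genes, 0.251 with all transcript clusters and 0.50 with the stricter filter. Exercise in knockout fell from 38 calls to 12 with all clusters, by construction a test of more features. Without a trend in the prior, exercise in knockout gave 24 and genotype averaged over exercise 42. With array weights, exercise in wild type gave 127, exercise in knockout 83, knockout against wild type, exercised 89, exercise averaged over genotypes 348, genotype averaged over exercise 193 and genes near Ddit4 1. With only the groups compared, which has fewer arrays, exercise in knockout gave 25 and knockout against wild type, exercised 13.

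Analysis of variance without moderation gave 12 for exercise in wild type, 0 for exercise in knockout (1227 at limma's unadjusted p under 0.05), 1 for knockout against wild type, sedentary, 1 for knockout against wild type, exercised, 67 for exercise averaged over genotypes and 23 for genotype averaged over exercise. At an adjusted p under 0.10, the counts in the same order were 121, 79, 30, 41, 349 and 140, and genes near Ddit4 had 1. At an unadjusted p under 0.05 with at least 1.5-fold change they were 183, 174, 117, 99, 123 and 47, and the difference of exercise effects had 168. Both sets follow from the thresholds.

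With both arrays that stood apart left out, knockout against wild type, exercised gave 45 and genotype averaged over exercise 139; the others were 74 for exercise in wild type, 55 for exercise in knockout, 20 for knockout against wild type, sedentary and 204 for exercise averaged over genotypes. The immediate-early list's difference of exercise effects, -0.22 over all arrays, reversed to 0.013 with both left out. With 1 array left out it ranged from -0.309 (without wild-type exercised replicate 3) to 0.028 (without wild-type exercised replicate 1), a reversal; the cause was not tested. Over the 220 genes, the difference of exercise effects gave 7.

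Leaving out 1 array at a time, counts ranged from 46 to 90 for exercise in wild type, 16 to 71 for exercise in knockout, 6 to 27 for knockout against wild type, sedentary, 5 to 40 for knockout against wild type, exercised, 144 to 220 for exercise averaged over genotypes and 38 to 149 for genotype averaged over exercise. The difference of exercise effects stayed at 0 calls by limma (620 at an unadjusted p under 0.05 over all arrays) and genes near Ddit4 at 0. The agreement ranged from 0.309 to 0.404. A group reduced to 2 arrays was assumed to vary like the others. No paired analysis was possible because the labels give no number that pairs arrays across groups. Signal near background limits genes such as Rab6b and Rnase2a, whose sedentary wild-type levels of 4.43 and 3.09 lay below the table median.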

Other observations

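The added alternative that leaves out both arrays that stood apart was chosen after the data were seen; the splits of the arrays were planned.

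Single members of lists that did not pass were called for the averaged exercise effect. Musk, the receptor kinase that organises the neuromuscular junction, rose by 0.53 (SE 0.11, adjusted p = 0.0261), the only 1 of 17 measured junction genes called, and the list's median was -0.01 (camera adjusted p = 0.908). Among cytokine, chemokine and myokine genes, the interleukin 6 receptor gene Il6ra rose by 0.59 (SE 0.09, adjusted p = 0.00176), 1 of 15 measured members called, with a list median of -0.01 (camera adjusted p = 0.418). Il6 itself was too dim to be tested. Hk2, a member of the hypoxia and glycolysis lists, rose by 0.73 (SE 0.10); the hypoxia-inducible median was 0.10 (camera adjusted p = 0.0597) and the glycolysis and glycogen median -0.02 (camera adjusted p = 0.738). Notch3, a receptor of pericytes, fell by 0.46 (SE 0.11), the 1 of 10 members called in the smooth muscle and pericyte list, which passed only with the preset correlation. The 4 neutrophil and 2 red blood cell markers that passed the filter had medians of 0.04 and 0.08, and were not tested as lists.

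Other splits of the arrays were fitted in the same way. Exercise averaged over genotypes gave 220 genes in the real split and at most 2 in the other 99 of 100 splits, and genotype averaged over exercise gave 75 and at most 2, so that 1 of 100 splits gave as many in each case and a random grouping of arrays is excluded as the source at a share under 0.05. For the comparisons of 3 arrays against 3, 10 splits are too few for a share under 0.05; the real split was the 1 of 10 with the most calls. It gave 78 against at most 1 for exercise in wild type, 38 against at most 5 for exercise in knockout, 19 against at most 1 for knockout against wild type, sedentary, and 24 against at most 0 for knockout against wild type, exercised. For the difference of exercise effects, limma called 0 genes in the real split (620 at an unadjusted p under 0.05), a count that 100 of 100 splits must reach, so the splits decide nothing there. The highest count, 230, came from a split with all 6 exercised arrays on one side of the contrast, which rebuilds the exercise effect.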
